A study of Mus musculus with 12 samples.

How the data were processed

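Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done, per the labels' protocols, on cells sorted from mouse bone marrow of the C57BL/6 strain and on HPC7, a mouse haematopoietic progenitor cell line grown with stem cell factor. The sorted populations were haematopoietic stem cells (HSC; lineage-negative, Sca-1-positive, Kit-positive, CD34-negative and Flt3-negative; 15000 cells) and megakaryocyte-erythroid progenitors (MEP; 30000 cells), each from wild-type animals and from animals heterozygous for Mof. Libraries were made from nuclei after sonication and sequenced on an Illumina instrument, per the labels. The series held 12 samples. Peak lists of 5 of them were analysed here, namely MOF in wild-type and heterozygous HSC, MOF in wild-type and heterozygous MEP, and GATA1 in HPC7. The other 7 samples, which were 6 input libraries and 1 H4K16ac library of HPC7, were not analysed here.

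Bowtie2 2.3.0.1, deepTools and MACS2 are named with the genome build mm10, per the submitters' processing notes. The settings of these tools, the versions of deepTools and MACS2, the duplicate filter, the removal of blacklisted regions and which input served as background for which list are not given in the sources used here. Each list belongs to 1 sample, and nothing in the sources used here says that samples were pooled.

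The lists came in 3 layouts, and these set what could be compared. The deposited wild-type MOF lists give each peak as a summit of 1 bp with a −log10 value per peak from the authors' caller. No header states what that value is. Its minimum in each wild-type list lay just above 1.3, as a −log10 q-value with a threshold of 0.05 would give, and it was read in that way. The deposited heterozygous MOF lists are intervals with the authors' fold enrichment, −log10 p, −log10 q, a whole-number score and a summit position per peak. In these files the score that the authors deposited equals 10 times the −log10 q without its decimals. The deposited GATA1 list gives, as its only other values, the start and end of each interval, without a score, so its intervals were ranked by width. All per-peak values are the authors' and were used only to describe or rank peaks within a list. Read numbers per library are not given in the sources used here, so the depth behind each list is unknown. The number of peaks in a list moves with depth and with the caller's settings.

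Each wild-type summit was extended by 150 bp on each side to 301 bp, close to the median width of 299 bp in the heterozygous HSC list. The other intervals were used as deposited. Peaks of a pair of lists were shared if they overlapped by at least 1 bp. The observed number was compared with 1000 random placements of the first list, in which each peak kept its width and its chromosome or scaffold. On a scaffold or the mitochondrial genome a peak could move only within the stretch up to the last peak of any list. Random overlaps are therefore frequent on such short sequences, and folds over random are not comparable between pairs of lists. The p-value was one-sided, and 0.001 is the smallest that 1000 placements can give. Benjamini-Hochberg adjustment was done over the 4 overlaps among MOF lists and over the 4 overlaps with GATA1. The extension was chosen after the file layouts were seen and before any overlap was computed. Coordinates are printed 1-based on mm10.

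Genes came from the RefSeq annotation of GRCm38.p6, the same build, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. This table holds gene starts and ends without strand, exons or sequence. The tests that had been planned around transcription start sites were therefore run around gene ends, meaning either annotated end of a protein-coding gene. The planned division into exon and intron and the planned search for GATA motifs and GC content were not run. A peak was called at a gene end if its midpoint lay within 1 kb of one. Chromosome lengths were approximated by the span from the first to the last annotated gene.

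Shares are given with 95% Wilson intervals, which cover counting error only. Shares of peaks were compared between lists with two-sided Fisher's exact tests. Gene-end shares were also compared with 1000 random placements, for which 0.002 is the smallest two-sided p, or 0.0025 after adjustment over the 5 lists. Scores of peaks called again and not called again were compared by the difference of medians in a two-sided permutation test with 100000 resamples, for which 1e-05 is the smallest p. For 14 gene lists fixed before the data were examined, the protein-coding genes with a peak midpoint within 5 kb of a gene end were counted and compared with all protein-coding genes by one-sided Fisher's exact tests. Benjamini-Hochberg adjustment was done over the 70 tests of lists and libraries. Chromosome shares were compared with the share of length by exact binomial tests, adjusted over 105 tests. With 1 library per group, every p-value compares peak lists and not genotypes or cell types, and there is no replicate check on any difference.

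The overlap and gene-list procedures were tested on simulated data. With 100 shared peaks planted between lists of the sizes of wild-type HSC and MEP, 20 of 20 simulations were called, and 0 of 20 without planted peaks. With 10 planted between lists of the sizes of wild-type and heterozygous MEP, 20 of 20 were called, and 0 of 20 without. The simulated peaks were all 301 bp wide and placed uniformly along chromosomes, as in the random placements themselves. These runs therefore check the procedure and cannot show how often it calls lists that are concentrated at gene ends. For a list of 84 genes simulated like the ribosomal protein genes in wild-type HSC, 47 of 50 simulations were called when 20% of members against 8% of all genes had a peak, and 4 of 50 when both were at 8%. Genes were drawn independently there and called without adjustment, so clustered genes and the adjusted calls were not covered.

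The alternatives covered the overlap required, a distance of 1 kb, the peaks above the median score of each list, lists of equal length, a circular shift, placement that keeps the distance to a gene end, other windows, expectation from gene numbers, and, for the overlaps and the peaks called again, removal of peaks found in 4 or 5 of the 5 lists. A peak was removed by its own overlaps, so other peaks inside the same recurrent region could remain. Further alternatives were added after the data were seen, namely summits not extended or extended by 500 bp, autosomes and X only, removal of peaks in the GATA1 list, removal of peaks found in 4 or 5 lists for location, gene lists and chromosomes, and peaks counted in place of genes. Genes and regions are named by a rule fixed before the data were examined. It takes every member of the short gene lists with a peak within 5 kb, the 4 members with the highest-scoring peaks of the 5 long gene families, the 10 highest-ranked peaks of each list, and the 10 highest of the shared and unshared peaks of each main pair, from which examples are given, and Kat8 in every list. Some of the genes that the rule takes are not reported here. Any other name was chosen after its values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.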

Results

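MOF, the product of Kat8, is an acetyltransferase of histone H4 that deposits the mark H4K16ac. Its chromatin occupancy was mapped by ChIP-seq in haematopoietic stem cells (HSC) and megakaryocyte-erythroid progenitors (MEP) sorted from the bone marrow of wild-type and Mof heterozygous mice. GATA1, the main erythroid transcription factor, was mapped in the progenitor line HPC7. The 5 peak lists came from 1 library each. Every test below therefore compares peak lists, and none of the differences has a replicate check. Sequencing depth is unknown.

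Most MOF peaks were called in the wild-type libraries. The list held 1876 peaks in wild-type HSC and 898 in wild-type MEP, against 338 in heterozygous HSC and 64 in heterozygous MEP. The wild-type list was 5.55 times as long as the heterozygous list in HSC and 14 times as long in MEP. The GATA1 list held 477 intervals. The authors' median −log10 value per peak was 5.27 in wild-type HSC, 7.66 in heterozygous HSC, 5.61 in wild-type MEP and 9.69 in heterozygous MEP. The heterozygous intervals had a median width of 299 bp in HSC and 211.5 bp in MEP, with median fold enrichments of 4.26 and 6.45. The GATA1 intervals had a median width of 263 bp.

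Kat8 itself, the gene that is heterozygous in the mutant animals, carried peaks in every list. The gene lies on chromosome 7 from 127912517 to 127925838. Its body held 3 peaks in wild-type HSC, 1 in heterozygous HSC, 4 in wild-type MEP and 5 in heterozygous MEP. The GATA1 list from HPC7 held 5 intervals there as well, and all 18 Kat8 peaks overlapped a Kat8 peak of another list. In heterozygous MEP the interval from 127915236 to 127915610 ranked 1 of 64 by −log10 q (98.4, 11.6-fold enrichment), and the interval at the lower-coordinate end of the gene, from 127912488 to 127912788, ranked 2 (88.7, 7.00-fold). In heterozygous HSC the single Kat8 interval, from 127912403 to 127912781, ranked 85 of 338 with a −log10 q of 29.3. No other protein-coding gene held more than 1 peak in heterozygous MEP or more than 2 intervals in the GATA1 list. A peak list does not measure Kat8 expression or gene dose, so these values do not check the genotype labels.

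**Figure D1:**
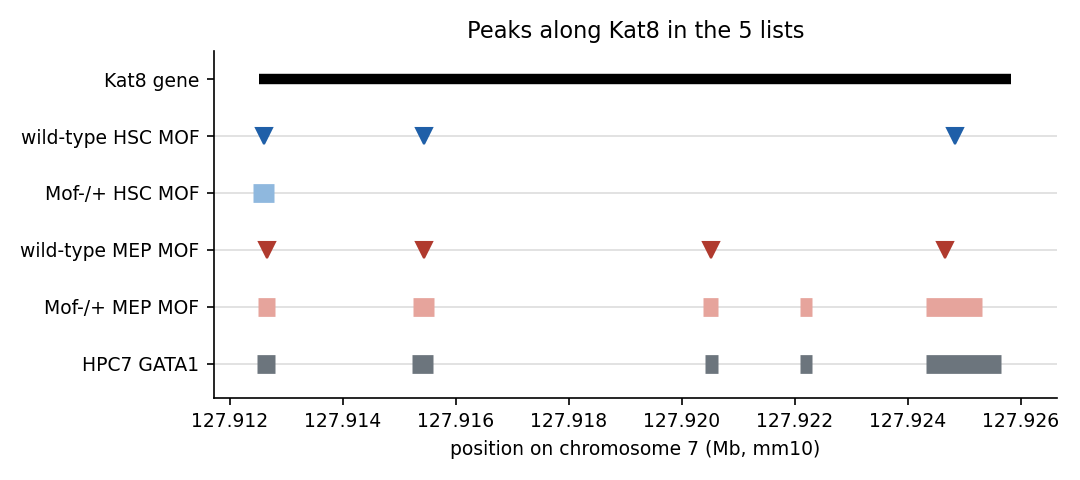
Positions of the peaks along Kat8 (black bar) on chromosome 7 of mm10, with 1 row per list, triangles for wild-type summits of 1 bp and boxes for intervals drawn to scale. The 18 peaks fall at 5 positions that recur between lists, including the list of GATA1 in HPC7.

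MOF peaks in wild-type cells lay at the ends of protein-coding genes far more often than random positions, and in HSC most of them did. Within 1 kb of a gene end were 1146 of 1860 peaks in wild-type HSC (61.6%, 95% interval 59.4 to 63.8) and 419 of 865 in wild-type MEP (48.4%, 45.1 to 51.8), against 3.25% and 3.19% at random positions. The corresponding share was 24.9% in heterozygous HSC (73 of 293, 20.3 to 30.2) and 4.92% in heterozygous MEP (3 of 61, 1.69 to 13.5). GATA1 intervals were also seldom at gene ends, at 6.22% (29 of 466). Of the GATA1 intervals, 41.4% lay elsewhere inside gene bodies and 41.2% outside any annotated gene, shares that were not compared with random placement.

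The gene-end share was higher in wild type than in heterozygotes in both HSC (odds ratio 4.84, 3.63 to 6.49, adjusted p = 8.3e-32, Fisher's exact test) and MEP (18.2, 5.83 to 91.1, exact test, adjusted p = 6.3e-13). Among wild-type lists it was higher in HSC than in MEP (1.71, 1.45 to 2.02, exact test, adjusted p = 1.3e-10), and it was lower for GATA1 than for MOF in wild-type MEP (0.0706, 0.0458 to 0.106, adjusted p = 9.6e-63). Against random placement the gene-end share was 19.0-fold in wild-type HSC, 15.2-fold in wild-type MEP, 8.30-fold in heterozygous HSC and 2.01-fold for GATA1, each with adjusted permutation p = 0.0025, the smallest possible. In heterozygous MEP it was 1.65-fold (permutation p = 0.529). The odds ratio between wild-type and heterozygous HSC was 15.8 among peaks above the median score of each list and 3.06 without peaks in the GATA1 list. In MEP it was 11 above the median score, and without peaks in the GATA1 list its lower 95% limit was 7.62, with 0 of 27 heterozygous peaks left at gene ends.

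**Figure D2:**
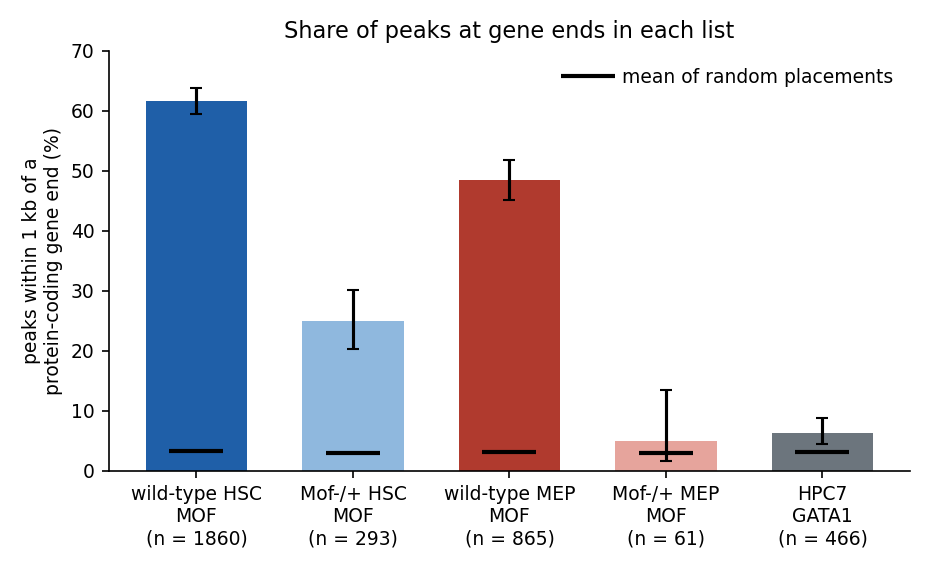
Share of peaks within 1 kb of an annotated end of a protein-coding gene in each list, in percent, with 95% Wilson intervals and the mean of 1000 random placements as black dashes. The share is 61.6% in wild-type HSC and 48.4% in wild-type MEP, and 24.9%, 4.92% and 6.22% in heterozygous HSC, heterozygous MEP and for GATA1.

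To ask which MOF sites stem cells and progenitors have in common, the wild-type lists were compared. Of the wild-type HSC peaks 278 overlapped a wild-type MEP peak (14.8%, 13.3 to 16.5), and 277 of the MEP peaks overlapped an HSC peak (30.8%, 27.9 to 33.9). The shared peaks with the highest scores in HSC lay inside Zc3h7a (chromosome 16, position 11144112, −log10 value 57.1), inside Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123462003, 44.8), 282 kb from Pex2 (43.9), inside Cdk8, a kinase of the Mediator complex (35.7), at the lower-coordinate end of Kat8 (34.4), and inside Filip1l, Peak1 and Jarid2 (33.5, 29.0 and 24.8). All 10 of the highest shared peaks belonged to regions that occurred in 4 or 5 of the 5 lists, GATA1 included. By gene, 1865 genes had a peak within 5 kb of an end in HSC and 745 in MEP. Both lists held 333 of these, against 63.5 expected for independent lists (odds ratio 10.3, p = 7.5e-162, Fisher's exact test). A single peak can count for several neighbouring genes, so genes are not independent units and this p-value is descriptive only.

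The highest peaks found in HSC and not in MEP occurred in no other list. Among them were peaks next to Cd209a (chromosome 8, 3754555, 28.5), near Atp13a2 (21.4), at the ends of Tpt1 (chromosome 14, 75845196, 20.3), Gdf15, a stress-induced cytokine (chromosome 8, 70629867, 19.1), Scaf11 (18.6), Pip4k2b (18.1), the chromatin remodelling factor Rsf1 (17.7) and the mismatch repair gene Msh6 (16.9), and farther from Ccr1 (17.6). None of the 10 highest peaks in MEP that overlapped no HSC peak lay at a gene end. Among them were a position in the non-coding gene Gm34259 (chromosome 17, 4626351, 202), a ribosomal RNA repeat (Rn18s-rs5, 82.3) and a mitochondrial position (65.6). A further 6 lay in the first stretch of chromosome 9, between 3003494 and 3034998, outside any annotated gene. The Gm34259 site was also in both heterozygous lists and the GATA1 list, so it was not particular to MEP. The ribosomal RNA repeat and the start of chromosome 9 belong to regions found in all 5 lists, with 11 wild-type HSC peaks in the first 4 Mb of chromosome 9, so there only the extended summits did not overlap. The number shared exceeded all 1000 random placements (mean 2.16, permutation p = 0.001, the smallest possible). The excess was 129-fold with uniform placement and 23.9-fold with placement that kept each peak's distance to a gene end.

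Histone genes stood out among the fixed gene lists in both wild-type libraries. A peak lay within 5 kb of 33 of 71 histone genes in HSC (46.5%, 35.4 to 58.0, against 8.52% of all protein-coding genes) and of 49 of 71 in MEP (69.0%, 57.5 to 78.6, against 3.40%). This was 5.45-fold (exact test, adjusted p = 1.0e-15) and 20.3-fold (adjusted p = 1.1e-53) above background. The highest-scoring peaks were next to H4c3 and H1f6 (11.9), H3c6 (8.68) and H2bc6 (8.51) in HSC, and next to H4c17, H2ac23 and H2bc23 (16) and H4c18 (13.7) in MEP. In tests added after these counts were seen, 29 genes were in both libraries, 4 in HSC alone and 20 in MEP alone (exact McNemar test, p = 0.0015). Histone genes are clustered, so 1 peak can count for several, and with peaks counted in place of genes the excess was 4.17-fold in HSC and 13.1-fold in MEP (permutation test, adjusted p = 0.012 in both). Of all peaks, 31 of 865 MEP peaks (3.58%) and 22 of 1860 HSC peaks (1.18%) lay within 5 kb of a histone gene end (odds ratio 3.10, 1.73 to 5.66, adjusted p = 0.00014, Fisher's exact test).

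Ribosomal protein genes were over-represented as well, with 29 of 84 in HSC (34.5%, 4.05-fold, exact test, adjusted p = 5.2e-10) and 19 of 84 in MEP (22.6%, 6.65-fold, adjusted p = 7.4e-10). The lists had 12 of these genes in common, among them Rpl3, Rpl5, Rpl27, Rps19 and Rps23. The highest peaks were at Rpl5 (12.4), Rpl26 (12.1), Rpl3 (7.49) and Rpl19 (7.28) in HSC and at Rpl41 (9.59), Rps23 (6.77), Rpl27 (6.67) and Rps19 (6.2) in MEP. The share of peaks near ribosomal protein genes was 1.56% in HSC and 2.20% in MEP, a difference that did not pass the test (odds ratio 1.42, 0.747 to 2.63, adjusted p = 0.27, Fisher's exact test).

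Of the 12 genes for subunits of the MOF-containing complexes, 5 had a peak in wild-type HSC (4.89-fold, exact test, adjusted p = 0.025). These were Kat8, the NSL complex members Kansl2, Kansl3 and Mcrs1, and Msl1, whose peak lay nearer to Casc3. In wild-type MEP there were 2, Kat8 and the NSL member Phf20 (exact test, adjusted p = 0.35), a list that passed with peaks counted in place of genes (7.91-fold, permutation test, adjusted p = 0.026), where 3 of the 4 peaks were in Kat8. The call in HSC was lost without peaks found in 4 or 5 lists, which include Kat8 (3.92-fold, exact test, adjusted p = 0.15), and with a window of 20 kb (2.96-fold, adjusted p = 0.13).

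The lineage lists did not pass the test in either wild-type library. Erythroid genes with a peak were 3 of 39 in HSC, namely Bcl2l1 (8.05), Nfe2 (6.89) and Zfpm1 (5.99), and 4 of 39 in MEP, among them the transferrin receptor gene Tfrc (8.35), Zfpm1, which encodes the GATA1 cofactor FOG1 (8.28), and the carbonic anhydrase gene Car1 (7.56). For MEP the raw p of the exact test was 0.043 and the adjusted p 0.28. Stem cell genes with a peak were 4 of 30 in HSC, the transcription factor genes Lyl1 (7.25), Mecom (5.94), Runx1 (3.61) and Hlf (3.30), and 0 of 30 in MEP (exact test, adjusted p = 0.92 in HSC; the difference between the libraries was not tested). Megakaryocyte genes were 2 of 20 in HSC, Nfe2 and Runx1, and 0 of 20 in MEP. Of the 7 heptad factors, which act together in blood progenitors, Lyl1 and Runx1 had a peak in HSC (exact test, adjusted p = 0.50).

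The lists of other cell types did not pass the test either. Myeloid genes with a peak were 0 of 20 in HSC and 3 of 20 in MEP (Fcgr3, Cebpe and Cd68, whose peak lay nearer to Mpdu1; 4.41-fold, exact test, raw p = 0.029, adjusted p = 0.25). The Fcgr3 peak (7.03), inside that gene, is also counted below near transfer RNA and microRNA genes. The lymphoid list had Cd3g in HSC and Rag2 in MEP, both with a peak nearer to another gene, Ube4a and Iftap. Mast cell and basophil genes (0 of 10) and stromal and endothelial genes (0 of 12) had no peak in any list. Genes of oxidative phosphorylation were 12 of 82 in HSC (exact test, raw p = 0.045, adjusted p = 0.28) and 2 of 82 in MEP. The highest peak counted for them, near Sdhb (21.4), lay nearer to Atp13a2, and those of Ndufs1 (6.92) and Ndufa7 (5.80) nearer to Eef1b2 and Rps28. Proteasome genes were 4 of 39 in HSC, with Psmd3 (9.56) and Psma1 (8.13) highest, and 3 of 39 in MEP, with Psmd5 (9.09) and Psmd3 (5.68) highest. Of 1106 olfactory receptor genes, 0 had a peak in HSC and 2 in MEP.

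**Figure D3:**
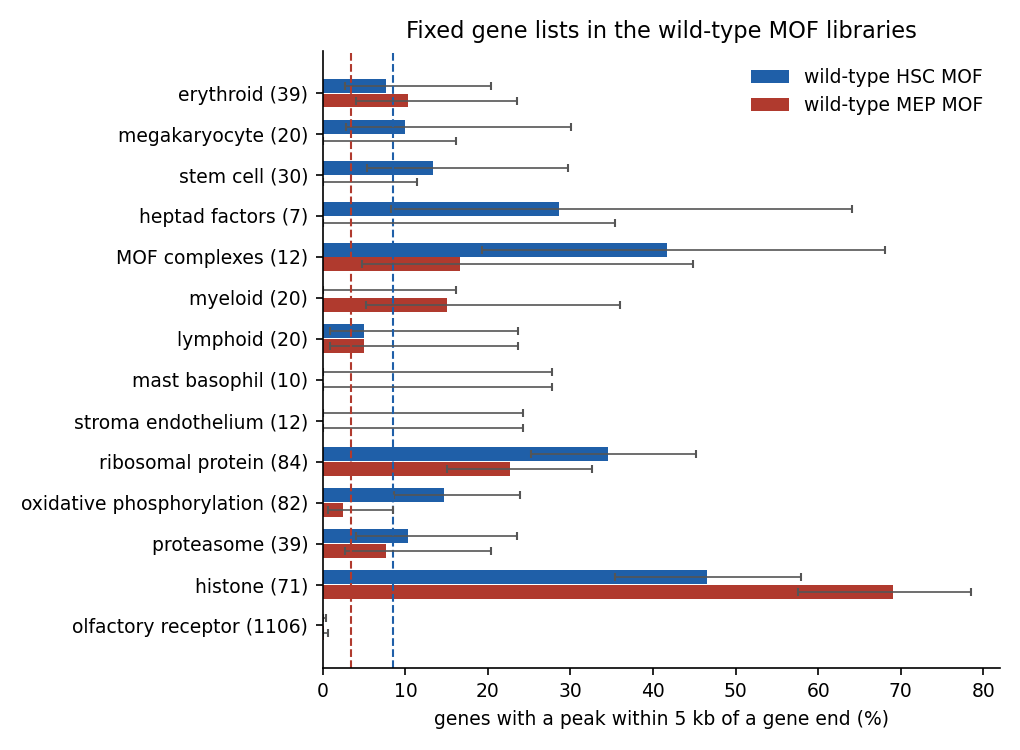
Percent of the genes of each fixed list with a wild-type MOF peak within 5 kb of a gene end, with 95% Wilson intervals, and the share of all protein-coding genes as dashed lines in the colour of the library. Numbers of genes are in brackets, and the histone genes reach 46.5% in HSC and 69.0% in MEP.

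The next question was which MOF sites of wild-type HSC were also called in heterozygous HSC. Only 91 of the 1876 wild-type peaks overlapped a heterozygous peak (4.85%, 3.97 to 5.92), which took up 88 of the 338 heterozygous peaks (26%, 21.6 to 31.0). The highest of the shared peaks were again inside Zc3h7a, Lars2, Cdk8, Filip1l, Peak1 and Jarid2 and at the lower-coordinate end of Kat8. Others were 282 kb from Pex2 and in the non-coding gene Gm36876, 61.1 kb from Axin2. Of the 10 highest, 9 belonged to regions in 4 or 5 lists. Wild-type peaks not called in the heterozygote included those near Cd209a, Mid1 (chromosome X, 169998184, 23.7), Nme1 (chromosome 11, 93968397, 22.2), Ewsr1 (20.6), Tpt1 and Gdf15, and the Kat8 summits at 127915427 (24.5) and 127924846 (22.6). None of the 10 highest heterozygous peaks that overlapped no wild-type peak lay at a gene end. The first of them was at Gm34259 (chromosome 17, 4626160 to 4626600, −log10 q 92.0, 29.8-fold enrichment), a site also in both MEP lists and the GATA1 list. In the first stretch of chromosome 9 lay 5 of the 10. That region was found in all 5 lists, with 11 wild-type HSC peaks in the first 4 Mb, so there only the single positions did not overlap.

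Peaks of wild-type HSC at gene ends were called again less often than peaks elsewhere, in a test added after the data were seen. At gene ends 27 of 1146 were called again (2.36%), against 52 of 714 elsewhere (7.28%; odds ratio 0.307, 0.184 to 0.504, p = 6.7e-07, Fisher's exact test). Outside the GATA1 list the shares were 2.19% and 3.37% (odds ratio 0.642, 0.346 to 1.19, exact test, p = 0.13). Histone genes were over-represented in heterozygous HSC, with 7 of 71 (17.4-fold, exact test, adjusted p = 2.2e-06) from 4 peaks, or 6.91-fold with peaks counted in place of genes (permutation test, adjusted p = 0.031). Of these genes 4 also had a wild-type peak, namely H1f2, H2ac19, H3c15 and H3f3b, named after their values were seen, but none of the heterozygous peaks near histone genes overlapped a wild-type HSC peak. Above the median score of the heterozygous list there were 0. Ribosomal protein genes were 2 of 84 (among them Rps29, exact test, adjusted p = 0.38). Lyl1 counted in both genotypes, but the wild-type summits (84700069 and 84701634 on chromosome 8) and the heterozygous interval (84705389 to 84705665) did not overlap. The overlap exceeded the random mean of 4.45 peaks 20.5-fold (permutation p = 0.001, the smallest possible). On autosomes and X alone it was 577-fold. Peaks on scaffolds, which could move only over a short stretch, then no longer added to the random mean.

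In MEP 27 of the 898 wild-type peaks overlapped a heterozygous peak (3.01%, 2.07 to 4.34), and they took up 27 of the 64 heterozygous peaks (42.2%, 30.9 to 54.4). The highest shared peaks were at Gm34259 (wild-type −log10 value 202), at 3 positions in Kat8 (135, 78.1 and 58.2) and 61.1 kb from Axin2 (90.7). Others were at the start of chromosome 9 (87.5), in the ribosomal RNA repeat (82.3), inside Numa1 (82), 282 kb from Pex2 (52.7) and inside Filip1l (45.4). All 10 belonged to regions in 4 or 5 lists. None of the 10 highest wild-type peaks not called again lay at a gene end, and 6 of them were at the start of chromosome 9, a region found in all 5 lists. The highest heterozygous peaks not in wild type lay inside Kctd16 (chromosome 18, 40308064 to 40308275, −log10 q 25.4, 4.91-fold), Aida (14.2) and Bckdhb (13.0), at a position in Kat8 without a wild-type summit (17.5), and in the ribosomal RNA repeat, at other positions than the wild-type summit there.

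Of the wild-type MEP peaks at gene ends, 2 of 419 were called again in heterozygous MEP (0.477%), at Kat8 and Lars2, against 22 of 446 elsewhere (4.93%; odds ratio 0.0924, 0.0105 to 0.381, p = 3.4e-05, Fisher's exact test added after the data were seen). Within score deciles the pooled odds ratio was 0.411 (0.10 to 1.69, permutation p = 0.26), so the call was lost at like scores. In HSC the pooled value was 0.315 (0.195 to 0.510). Outside the GATA1 list these were 0 of 416 and 2 of 369 (exact test, p = 0.22). No histone or ribosomal protein gene had a peak in heterozygous MEP. The only fixed list past the threshold there, the MOF complexes, rested on Kat8 alone (1 of 12, exact test, adjusted p = 0.044). Adjusted over the lists of this library alone, it did not pass (exact test, adjusted p = 0.061). The call was also lost with a window of 20 kb and without peaks in the GATA1 list. The overlap exceeded the random mean of 0.295 peaks 91.5-fold (permutation p = 0.001, the smallest possible). It was 1263-fold on autosomes and X. Without peaks in the GATA1 list 2 peaks were shared, which was 286-fold (permutation p = 0.001).

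**Figure D4:**
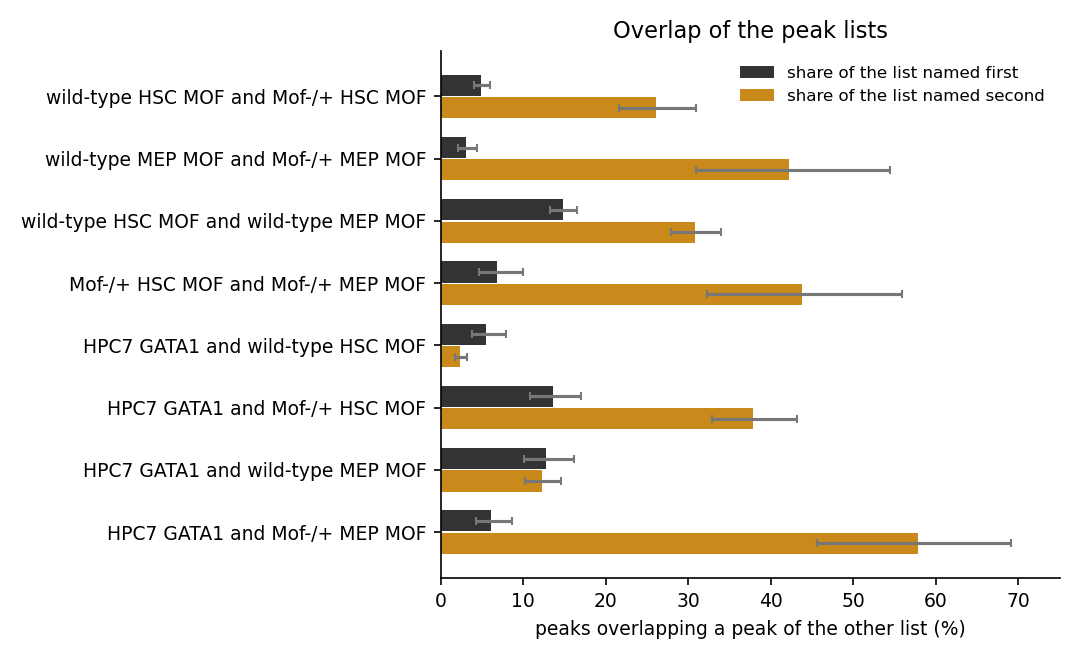
Percent of the peaks of each list that overlap a peak of the other list by at least 1 bp, for 8 pairs of lists, with 95% Wilson intervals. Black bars give the share of the list named first and yellow bars that of the list named second, which reaches 57.8% for heterozygous MEP peaks in the GATA1 list and 2.35% for wild-type HSC peaks.

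The share of wild-type peaks called again was higher in HSC than in MEP, 4.85% against 3.01% (odds ratio 1.64, 1.05 to 2.65, p = 0.027, Fisher's exact test). With all 4 MOF lists at the length of the shortest, the order turned, with 14.1% in HSC and 20.3% in MEP (odds ratio 0.642, exact test, p = 0.48). On autosomes and X the odds ratio was 1.46 (exact test, p = 0.12), and above the median score of the wild-type lists 1.14 (p = 0.64). It rose to 6.06 without peaks found in 4 or 5 lists (exact test, p = 2.4e-05) and to 11.03 without peaks in the GATA1 list (p = 4.0e-06). In both cell types the peaks called again had scored higher in the wild-type list. The median −log10 value was 7.59 for the 91 called again and 5.23 for the others in HSC (difference 2.36), and 31.2 for the 27 called again and 5.51 for the others in MEP (difference 25.7), each with permutation p = 1e-05, the smallest possible. Without peaks found in 4 or 5 lists the difference in MEP was 10.4 (permutation p = 0.021). It rested on few peaks, since on the annotated chromosomes 0 of 417 at gene ends and 4 of 412 elsewhere were then called again.

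The heterozygous lists shared 23 of 338 HSC peaks (6.8%, 4.58 to 10.0) and 28 of 64 MEP peaks (43.8%, 32.3 to 55.9), which was 30.1-fold above random placement (permutation p = 0.001, the smallest possible). These included Gm34259, Zc3h7a, Filip1l and the lower-coordinate end of Kat8. By gene, 5 of the 8 genes with a peak near an end in heterozygous MEP were among the 124 of heterozygous HSC. Without peaks in the GATA1 list, 0 peaks were shared between the heterozygous lists.

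GATA1 sites of HPC7 were compared with the MOF lists to ask whether they coincide. GATA1 intervals overlapped 61 times with wild-type MEP (12.8% of 477, 10.1 to 16.1), 65 times with heterozygous HSC (13.6%), 29 times with heterozygous MEP (6.08%) and 26 times with wild-type HSC (5.45%). Seen from the MOF lists, peaks in the GATA1 list made up 57.8% of heterozygous MEP (37 of 64, 45.6 to 69.1) and 37.9% of heterozygous HSC (128 of 338, 32.9 to 43.2), but 12.2% of wild-type MEP (110 of 898) and 2.35% of wild-type HSC (44 of 1876, 1.75 to 3.13). All 4 overlaps exceeded random placement (14- to 50.9-fold, adjusted permutation p = 0.001, the smallest possible). The overlap with wild-type HSC fell to 0 without peaks found in 4 or 5 lists. The widest GATA1 interval was the first 38291 bp of chromosome 9 from position 3000001, followed by intervals of 29980 and 14527 bp on the scaffold JH584304.1 and 5784 bp at the ribosomal RNA repeat on chromosome 17. In the first 4 Mb of chromosome 9 lay 35 heterozygous HSC, 25 wild-type MEP, 11 wild-type HSC and 2 heterozygous MEP peaks. On JH584304.1 there were 29, 29, 11 and 2, in the same order. Each wide interval counts once for GATA1 but can overlap many MOF peaks, so the MOF shares above do not count separate sites. None of the 39 erythroid genes, and none of the megakaryocyte, stem cell or heptad genes, had a GATA1 interval within 5 kb of an end, against 132 of 21887 protein-coding genes (0.603%). At that rate 0.235 erythroid genes would be expected, so a depletion was not detectable. The fixed-list genes that did have one were Kat8 and the olfactory receptor gene Olfr11.

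A set of 30 regions recurred across antibodies and cells, 14 in all 5 lists and 16 in 4. Those in all 5 lay inside Zc3h7a, Cdk8, Jarid2, Peak1, Lars2 and Filip1l, at the lower-coordinate end of Kat8, in the ribosomal RNA repeat and at the start of chromosome 9. The rest of these were 61.1 kb from Axin2, 282 kb from Pex2, 373 kb from Csmd1 and at 2 places on the scaffold JH584304.1. Peaks found in 4 or 5 lists by their own overlaps were 2.08% of wild-type HSC, 5.01% of wild-type MEP and 6.29% of GATA1. The shares were 13.0% in heterozygous HSC and 37.5% in heterozygous MEP. This count leaves out other peaks inside these regions that overlapped fewer lists. In heterozygous HSC, 44 of 338 peaks were counted, while the first 4 Mb of chromosome 9 held 35 peaks and JH584304.1 held 29.

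MOF is the mammalian relative of a Drosophila protein that acts on the male X chromosome, so the chromosomes were compared. The X chromosome held few peaks, and so did the Y chromosome in several lists. The X carried 23 of 1860 peaks in wild-type HSC (1.24%) and 17 of 865 in wild-type MEP (1.97%), against 6.31% expected from its length. The ratio to expectation was 0.196 (0.131 to 0.293, adjusted p = 2.8e-25, exact binomial test) in wild-type HSC, 0.311 (0.195 to 0.495, adjusted p = 3.3e-08) in wild-type MEP, 0.216 (adjusted p = 0.00078) in heterozygous HSC and 0.272 (adjusted p = 3.8e-05) for GATA1. Above the median score the ratio in heterozygous HSC was 0.360 (exact test, adjusted p = 0.29). Heterozygous MEP had 0 of 61 (exact test, adjusted p = 0.11). Against the number of genes the ratio was 0.280 in wild-type HSC and 0.445 in wild-type MEP. The Y ratio by length was 0.160 in wild-type HSC (exact test, adjusted p = 8.3e-15), 0.378 in wild-type MEP (adjusted p = 0.0015) and 0.0639 for GATA1 (adjusted p = 3.8e-05), and 1.02 in heterozygous HSC (adjusted p = 0.95). By gene number the Y ratio was 0.460 in wild-type HSC (exact test, adjusted p = 0.043), 1.09 in wild-type MEP (adjusted p = 0.91), 0.183 for GATA1 (adjusted p = 0.16) and 2.92 in heterozygous HSC (1.59 to 5.27, adjusted p = 0.015). Chromosomes 1 and 14 in wild-type HSC (0.707 and 0.700) and 1 and 3 for GATA1 (0.475 and 0.399) were also below expectation by length, but none of these passed by gene number (exact tests, adjusted p from 0.099 to 0.75). Chromosome 11 held 2.26 times the expected peaks in both wild-type lists (exact test, adjusted p = 6.8e-23 in HSC and 6.8e-11 in MEP), which was 1.39 and 1.38 times by gene number. Above expectation by length were also chromosomes 7, 10, 17 and 19 in wild-type HSC (1.3, 1.36, 1.62 and 1.5), 9 and 13 in wild-type MEP (1.83, with 25 of the 71 peaks in the first 4 Mb, and 1.49) and 6 in heterozygous HSC (1.73). By gene number chromosome 7 turned to 0.754 (exact test, adjusted p = 0.0048), and 17 and 19 did not pass (adjusted p = 0.22 and 1). Chromosome 9 held 3.65 times the expected peaks in heterozygous HSC (48 of 293, exact test, adjusted p = 3.2e-13), with 35 in its first 4 Mb. Chromosome 8 held 2.14 times the expected peaks in heterozygous HSC (exact test, adjusted p = 0.00078), 3.09 times in heterozygous MEP (adjusted p = 0.013) and 2.20 times for GATA1 (adjusted p = 5.1e-06). Above the median score the ratio turned to 0.792 in heterozygous HSC and did not pass in heterozygous MEP (2.61, exact test, adjusted p = 0.28). The sex of the animals is not given in the sources used here.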

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

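The tests of why the heterozygous lists were short and the restriction to autosomes and X were chosen only after the result was seen, whereas the comparison of HSC with MEP was planned. The share of wild-type MOF peaks called again gave an odds ratio of 1.64 for HSC over MEP by a direct test of the difference, between 1 library per group and with heterozygous lists of 338 and 64 peaks. It turned to 0.642 with equal list lengths (exact test, p = 0.48), and the call was lost above the median score (1.14) and on autosomes and X (1.46). Peaks also appeared on sequences that the comparisons of location and genes leave out, above the 3 counts that a count of 0 allows. There were 10 on the mitochondrial genome in heterozygous HSC, and on unplaced scaffolds there were 16 in wild-type HSC, 35 in heterozygous HSC, 32 in wild-type MEP and 11 in the GATA1 list.

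The heterozygous lists were short and held few peaks at gene ends (24.9% in HSC and 4.92% in MEP). The tables argue against regions that are also called with the GATA1 antibody as the whole reason: without them the odds ratio of the gene-end share, wild type over heterozygous, was 3.06 (2.23 to 4.22) in HSC and at least 7.62 by its lower 95% limit in MEP, where 0 of 27 remaining heterozygous peaks were at gene ends. A lower sensitivity of the heterozygous HSC library at every peak alike may still contribute, since outside the GATA1 list wild-type peaks at gene ends and elsewhere in the same score decile were called again at an odds ratio of 0.648 (0.364 to 1.15, permutation p = 0.18), an interval that includes both no difference and a large one. With all peaks the same ratio was 0.315 (0.195 to 0.510) in HSC and 0.411 (0.10 to 1.69) in MEP. The loss of 1 Mof copy stays open and cannot be told apart from a difference between libraries, because each genotype and cell type had 1 library.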

How the results depend on the processing

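The alternatives added after the data were seen are summits not extended or extended by 500 bp, autosomes and X only, removal of peaks in the GATA1 list, removal of peaks found in 4 or 5 lists for location, gene lists and chromosomes, and peaks counted in place of genes. Over 44 results, 233 of 252 values under an alternative kept their call, meaning the same side of the threshold with the same direction where either passed it, or a count within 1.5 times the reported one. These include 81 of 83 values for the overlaps, whose fold over random placement otherwise ranged widely with the definition. They also include the gene-end share of heterozygous MEP against random placement, which never passed and went from 1.65-fold to 0-fold without peaks found in 4 or 5 lists and without peaks in the GATA1 list. The overlap of the heterozygous lists fell to 0-fold without peaks in the GATA1 list, and that of GATA1 with wild-type HSC to 0-fold without peaks found in 4 or 5 lists, because no shared peak was left. The odds ratio of peaks called again, HSC over MEP, was 0.642 with equal list lengths, 1.14 above the median score (exact test, p = 0.64) and 1.46 on autosomes and X (p = 0.12), but 6.06 without peaks found in 4 or 5 lists and 11.03 without peaks in the GATA1 list. The over-representation of MOF complex genes in wild-type HSC was 2.96-fold at 20 kb and 3.92-fold both without peaks found in 4 or 5 lists and without peaks in the GATA1 list, and it no longer passed the threshold in these settings. In heterozygous MEP it was 67.6-fold at 20 kb (exact test, adjusted p = 0.11) and 0-fold without peaks in the GATA1 list, which removes Kat8. Histone genes in heterozygous HSC were at 0-fold above the median score. The number of gene lists past the threshold was 2 at 20 kb, where the heptad factors were added, and 0 above the median score in heterozygous HSC (1 as reported), 0 at 20 kb and 0 without peaks in the GATA1 list in heterozygous MEP (1 as reported), and 1 with peaks counted in place of genes for GATA1 (0 as reported), which was the MOF complex list through Kat8. In wild-type MEP it was 3 with peaks counted in place of genes, where the MOF complexes were added (2 as reported), and in wild-type HSC 2 in the 3 settings that lost the MOF complexes (3 as reported). Above the median score the X ratio in heterozygous HSC was 0.360, the chromosome 8 ratio 0.792 in heterozygous HSC (2.14 as reported) and 2.61 in heterozygous MEP (3.09 as reported), none of them past the threshold. Where no reason is given, the cause was not tested.

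Width in place of score gave no value, since every wild-type summit is 1 bp wide. The overlap of the heterozygous lists among peaks above the median score gave no fold, since no random placement overlapped. The GATA motif and GC alternatives were not run without a genome sequence, and any overlap with the window was run for the comparisons between lists and not for random placement. No paired analysis was possible because each group with a peak list has 1 library, and the labels number replicates only for the HPC7 input, as 1 and 2. Depth is unknown, so the number of peaks missed in each list cannot be bounded.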

Other observations

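The tests of small RNA genes, of Kat8 and of the share of GATA1 intervals in MOF lists were chosen only after the result was seen. The test of GATA1 intervals within 100 kb was written before its result was seen.

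Wild-type MOF peaks were frequent at genes for small nuclear RNAs and transfer RNAs, which the gene lists did not cover. Within 500 bp of a small nuclear RNA gene lay 25 of 1860 peaks in wild-type HSC (1.34%, 0.912 to 1.98) and 27 of 865 in wild-type MEP (3.12%, 2.15 to 4.50), 28.5 and 63.4 times the mean of random placements that kept the distance to a protein-coding gene end (permutation p = 0.001, the smallest possible; adjusted p = 0.005 over 20 tests). These peaks marked 24 annotated genes in HSC and 27 in MEP, 19 of them in both against 0.645 expected for independent sets. They included, in both libraries, Rnu1a1 of the spliceosomal U1 family (−log10 value of the nearest peak 10.7 in HSC and 21.1 in MEP), Rnu2-10 of the U2 family (4.71 and 23.7), Rnu11 of the minor spliceosome (14.3 and 12.7) and, from the U3 family that the annotation places in this class, Rnu3a (3.90 and 8.37) and Rnu3b1 to Rnu3b4, all named after their values were seen. Rnu12 (7.44) and Rnu7, the histone pre-mRNA processing RNA (3.23), had one in HSC, and Rn7sk had one in MEP (10.5). The U1 and U3b genes lie on chromosome 11 inside Tex14, whose body held 7 peaks in HSC and 6 in MEP. None of these peaks belonged to a region in 4 or 5 lists, and 0 peaks of heterozygous HSC, heterozygous MEP or GATA1 lay near a small nuclear RNA gene, which in lists of 293, 61 and 466 peaks leaves 95% Wilson upper limits of 1.29%, 5.92% and 0.818%.

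Transfer RNA genes were frequent near peaks in both wild-type lists, with 26 peaks in HSC (1.40%, 21.6-fold) and 24 in MEP (2.77%, 42.5-fold; permutation test, adjusted p = 0.005 in both). Of the 408 annotated genes, 35 were near a peak in HSC and 34 in MEP, with 11 in both against 2.92 expected for independent sets. Heterozygous HSC had 2 such peaks (0.683%, 0.187 to 2.45; 22.0-fold, permutation test, adjusted p = 0.010; the difference from wild type was not tested), and heterozygous MEP and GATA1 had 0. Transfer RNA and histone genes share clusters, but 0 of the 26 HSC peaks and 1 of the 24 MEP peaks also lay within 5 kb of a histone gene. Near small nucleolar RNA genes there were 7 peaks in HSC (4.36-fold, permutation test, adjusted p = 0.010) and 4 in MEP (5.43-fold, adjusted p = 0.015). Among the HSC peaks were those at Rpl6 (1.84), Rpl7a (3.00) and Rps20 (3.07), also counted above for the ribosomal protein genes. The excess in HSC is therefore not separate from that of the ribosomal protein genes. Near microRNA genes there were 10 in HSC (2.90-fold, permutation test, adjusted p = 0.014) and 4 in MEP (2.83-fold, adjusted p = 0.11). The difference between HSC and MEP was not tested for these classes.

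The peaks along the body of Kat8 recurred at the same positions between lists. The tables argue against occupancy picked up by the MOF antibody alone, since the GATA1 list held 5 intervals there. Copies of the Kat8 transcript sequence in the libraries are a candidate source that stays open: 18 of the 18 Kat8 peaks overlapped one of another list, and whether they lie on exons was not tested without an exon table. A region that is called with any antibody could not be excluded either. Of wild-type MEP peaks also in the wild-type HSC, heterozygous MEP and GATA1 lists, 1 of 3 in Kat8 and 12 of 13 elsewhere were also in heterozygous HSC (exact Fisher p = 0.071), a test with few regions.

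The GATA1 list held no erythroid gene within 5 kb. Sites far from the gene ends may account for this, but within 100 kb or in the gene body 1 of 39 erythroid genes (Slc25a37) had an interval, against 5.71% of other genes (odds ratio 0.435, 0.0107 to 2.58, exact p = 0.73), an interval too wide to decide. That the list holds regions called with any antibody stays open as well. Of its intervals, 16.6% were in 1 or more MOF lists, and how many the MOF libraries would have missed at their unknown depth cannot be said. No biological explanation was tested, since 1 GATA1 library was analysed.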
